A study of Mus musculus with 32 samples.

How the data were processed

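Hippocampus RNA of 32 mice was measured on Affymetrix whole-transcript arrays, with 4 animals for each of 4 genotypes at 4 and 9 weeks of age. Per the labels' protocols, the tissue was dissected on ice and snap frozen, RNA was extracted with PureZOL and an Aurum kit, sense-strand cDNA was made with the Ambion WT Expression kit, and the product was labelled with biotin. The deposited table holds log2 values of 35556 probe sets for each array, made with Affymetrix Expression Console 3.0 per the submitters' processing notes. The method of normalization, the annotation and any filter are not given in the sources used here. The array medians of the deposited log2 values lay between 7.94 and 8.02 at 4 weeks and between 7.69 and 7.77 at 9 weeks, so the ages look normalized separately. The number of arrays limits the precision.

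Each probe set was named by the gene table supplied for the array. Of 23410 probe sets listed there, 21789 had exactly 1 symbol, 1621 had several and were left out, and 12146 probe sets of the value table had none. The 21789 probe sets covered 19938 genes, and for the 999 genes with several probe sets the one with the highest mean was used. The gene identifiers of 21698 probe sets were found in a RefSeq table of assembly GRCm38.p6, and 0 symbols changed. Genes were kept when their mean over all arrays was above the 40th percentile of all probe-set means, a log2 value of 7.36, which left 13393. The build behind the array annotation is not given in the sources used here, so no coordinates are printed, and only gene lengths and the order of neighbours were taken from GRCm38.p6. Probe sets of microRNA host loci were tested but are not described.

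All 32 arrays were fitted once with limma 3.58.1 in R 4.3.3, with a mean for each of the 8 groups and a term for the run within each age. The run is a number in the array titles that divides each age into 2 sets of 8 arrays, with 2 arrays of each genotype in each. What the number marks is not stated. The fit gave 15 contrasts: each mutant against WT and each pair of mutants at each age, and the change of each mutant's difference from WT between ages. The age effect in WT was fitted with run as a random block, through duplicateCorrelation (consensus correlation 0.2501) and statmod 1.5.0, because runs lie within an age, so age cannot be told apart from run. P values were adjusted by Benjamini and Hochberg within each comparison, and genes with an adjusted p under 0.05 are called changed. Runs differed in 1551 genes at 4 weeks and in 4762 at 9 weeks.

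Choices of groups, tests, alternatives, gene lists and the rule for named genes were made before the data were examined. That rule took the 10 largest rises and the 10 largest falls of each mutant against WT among called genes with the same sign in both runs, the 5 largest in each direction of the other comparisons, and up to 4 members of each list with the smallest adjusted p. Genes named beyond it, such as members of the chromosome 6 stretch, genes shared by all mutants, Bdnf and Ttr, were chosen after their values were seen. Of 28 fixed lists, 27 with at least 5 tested genes were tested by camera with a preset correlation of 0.01, again with an estimated correlation, and by fry. Each list was also adjusted over its own members alone. They were markers of excitatory and inhibitory neurons, astrocytes, myelin, oligodendrocyte precursors, microglia, endothelium and mural cells, choroid plexus, thalamus and habenula, and striatum and neocortex. Further lists held immediate early genes, glucocorticoid-responsive genes, reported MeCP2-responsive genes, genes flanking Mecp2, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, glutamate receptors, GABA receptors, potassium channels and the synaptic vesicle cycle. The others held chaperones, interferon-stimulated genes, extracellular matrix, circadian clock, chromatin, and neuropeptides. The list of blood markers had 4 tested genes and was not tested. Each list was written from general knowledge of the field.

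The knockout signature score of an array is the mean log2 value of the 100 genes with the highest moderated t of KO against WT at the other age minus the mean of the 100 with the lowest, after subtracting the WT mean of its run. Scored arrays and arrays that chose the genes are different animals. Groups were compared by a two-sided exact permutation test over the 70 splits of 4 against 4 arrays, with the Benjamini-Hochberg adjustment over 6 pairs of mutants and over 6 comparisons with WT. The splits do not keep runs apart, so 36 splits within runs were added after the data were seen. Agreement between mutants was set against 100 simulated sets with shared WT arrays and no effect, both for correlations and for the overlap of equally long gene lists, and against WT arrays split in pairs. Gene length was taken for 12807 genes, 95.6% of those tested, and compared with fold changes by Spearman's rho. Figures were drawn with matplotlib 3.10.9, and tables were prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

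The fits were tested on simulated data of 13393 genes, in which 50 genes each were changed by 0.2, 0.4, 0.6 and 0.8 on the log2 scale. At 0.2 the share recovered was 62% for KO against WT at 4 weeks, 54% at 9 weeks, 46% and 56% for R270X against KO, 24% for the change of the KO difference between ages and 20% for age in WT. At 0.4 these shares were 92%, 92%, 92%, 98%, 84% and 80%, and at 0.6 they were 96% or higher. Between 1 and 12 unchanged genes were called. A simulated score of R270X at 0.5 of KO was recovered at 0.495 and 0.504.

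The alternatives tried were no run term, the replicate number as a block, each run alone, only the arrays compared, no filter and a 60th percentile filter, quantile normalization, median centring, the mean of probe sets, a variance trend with robust moderation, array weights, and each array of the compared groups left out. The gene lists were tested with a variance trend only, since camera offers no robust moderation. Leaving out WT replicate 2 at 9 weeks with G273X replicate 4 at 4 weeks, leaving out R270X replicates 3 and 4 at 4 weeks, and leaving out each array outside a comparison, were added after the data were seen. The first pair stood apart on the first principal component of its age. The closing part gives the effect of each alternative. Probe sets without a symbol were not used here.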

Results

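RNA of the hippocampus was measured on 32 Affymetrix whole-transcript arrays, 1 array per mouse. The mice were of the FVBx129 strain and carried 1 of 4 genotypes: wild type (WT), a null allele of Mecp2 (KO), and the null allele with a transgene that encodes MeCP2 truncated by the R270X or by the G273X mutation. MeCP2 is a protein that binds methylated DNA, and the human forms of these mutations cause neurological disease. Each genotype was sampled at 4 weeks and at 9 weeks with 4 animals, so each group mean below has n = 4, and this number of arrays limits the precision. The array titles divide each age into 2 runs with 2 arrays of every genotype, and 13393 genes were tested. None of the 21789 probe sets with exactly 1 symbol carried the name Mecp2 in the gene table. Those with several symbols were left out before this check, so the targeted gene is not analysed here.

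The first question was which transcripts differed from WT when MeCP2 was absent, at an age of 4 weeks. Irak1, a kinase of interleukin-1 and Toll-like receptor signalling, has its gene next to Mecp2. In KO animals Irak1 rose by 0.68 ± 0.04 (log2 fold change ± SE, n = 4 per group), a 1.60-fold change. All 3 mutants carry the null allele, so effects of the lost protein and of the allele on this neighbouring gene cannot be told apart. Pdlim1, an actin-associated adaptor, rose by 0.53 ± 0.05, and Crhbp, which binds corticotropin-releasing hormone, rose by 0.39 ± 0.05. The imprinted genes Dlk1 and Peg10 rose by 0.38 ± 0.05 and 0.41 ± 0.09, and Glp1r, the receptor of glucagon-like peptide 1, by 0.38 ± 0.07. Grp, a peptide transmitter, fell by 0.48 ± 0.06, the T-type calcium channel gene Cacna1g fell by 0.26 ± 0.05, and Stc1, a secreted glycoprotein, fell by 0.23 ± 0.05. Among 23 markers of inhibitory neurons, 2 rose (Pvalb, 0.24 ± 0.05, and Npy, 0.16 ± 0.04), 3 fell (Gad2, a GABA-synthesising enzyme, −0.15 ± 0.03, Reln, a guidance protein, −0.16 ± 0.04, and Lhx6, −0.19 ± 0.04), and 18 did not pass. When adjusted over the list alone, 5 rose and 6 fell. Of 48 genes reported elsewhere to respond to MeCP2, 4 rose (Irak1, Auts2, Cntn4 and Aff2) and 2 fell (Reln and Gad2). Of the 48, 10 rose and 4 fell adjusted over the list alone, and fry found movement upwards on balance (adjusted p = 0.00063). Camera with an estimated correlation did not call this list.

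In limma 104 genes passed an adjusted p of 0.05 in KO against WT at 4 weeks, 83 higher and 21 lower. All 104 had the same sign in both runs. The fitted difference is the mean over both runs, so called genes have little room to differ in sign between runs. The equal sign is therefore a weak check. Quantile normalization gave 71 higher and 56 lower. The count was 40 without WT replicate 1, 37 without KO replicate 2, 67 without KO replicate 3 and 59 without KO replicate 4. It was 28 without a run term. With 2 settings chosen after the data were seen, it was 222 without WT replicate 2 at 9 weeks, which lies outside the comparison, and 295 without that array and another that stood apart. Within the first run alone 1 gene passed, and within the second run 5. The count was also lower with only the arrays compared, without a filter and with median centring, as the closing part gives.

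The next question was whether a transgene with either truncated protein altered the difference from WT at 4 weeks. Irak1 rose by 0.70 ± 0.04 in R270X and by 0.69 ± 0.04 in G273X animals. Pdlim1 rose by 0.43 ± 0.05 and 0.32 ± 0.05, Dlk1 by 0.39 ± 0.05 and 0.44 ± 0.05, and Crhbp by 0.37 ± 0.05 and 0.26 ± 0.05. Grp fell by 0.45 ± 0.06 in R270X and by 0.38 ± 0.06 in G273X. The GABA receptor subunit gene Gabra3 fell by 0.29 ± 0.04 and 0.27 ± 0.04, and Rpp25, a subunit of ribonuclease P, fell by 0.30 ± 0.05 and 0.29 ± 0.05. Gap43, a growth cone protein, fell by 0.25 ± 0.05 in R270X, where G273X gave a value of −0.14 that did not pass. Naaa, a lysosomal hydrolase of lipid amides, rose by 0.21 ± 0.03 in R270X and 0.22 ± 0.03 in G273X.

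At 4 weeks 1 of 23 inhibitory markers rose in R270X (Npy) and 2 fell (Gad2 and Reln). In G273X 1 rose (Npy) and 1 fell (Reln). The numbers adjusted over the list alone were 1 higher and 6 lower in R270X, and 2 higher and 4 lower in G273X. Of 34 genes of the synaptic vesicle cycle, Rph3a, an effector of vesicle release, fell by 0.15 ± 0.03 in both genotypes, and Unc13b fell by 0.19 ± 0.04 in R270X. Camera placed that list lower in R270X (median −0.02, adjusted p = 0.00014, but adjusted p = 0.183 with an estimated correlation), and adjusted over the list alone 6 members were lower in R270X and 1 in G273X. Of 14 GABA receptor genes only Gabra3 passed in each genotype at 4 weeks, and 1, 1 and 2 were lower adjusted over the list alone. In G273X the median of those 14 genes was −0.07 (camera adjusted p = 1.8e-05, adjusted p = 0.174 with an estimated correlation). Choroid plexus, a tissue beside the hippocampus, had higher marker medians in mutants, at 0.40 in KO, 0.23 in R270X and 0.48 in G273X. None of its 18 markers passed among all genes, where limma gave Ttr, its main product, at 0.57, 0.39 and 0.57. Of these markers 9, 0 and 13 were higher adjusted over the list alone. The choroid plexus list had camera adjusted p = 3.8e-07, 0.0019 and 1.2e-14, and adjusted p = 0.588, 0.753 and 0.222 with an estimated correlation.

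In limma 70 genes passed in R270X at 4 weeks, 44 higher and 26 lower, and 26 passed in G273X, 13 higher and 13 lower. Every one of these genes had the same sign in both runs, a weak check, since the fitted difference is the mean over both runs. For R270X quantile normalization gave 59 higher and 66 lower, and median centring gave 11 higher and 36 lower. The R270X count was 30, 151 and 41 without WT replicates 1, 2 and 3, and 38, 35 and 39 without R270X replicates 2, 3 and 4. The G273X count was 14 without G273X replicate 4 and 42 without WT replicate 2 at 9 weeks, which lies outside the comparison. Without a run term the counts were 17 and 6. Within the first and the second run alone they were 4 and 2 for R270X, and 1 and 51 for G273X. Both counts were also far lower with only the arrays compared, and that of R270X without its replicates 3 and 4 together. Quantile normalization raised that of G273X, and leaving out the arrays that stood apart raised that of R270X. The closing part gives these values.

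**Figure D1:**
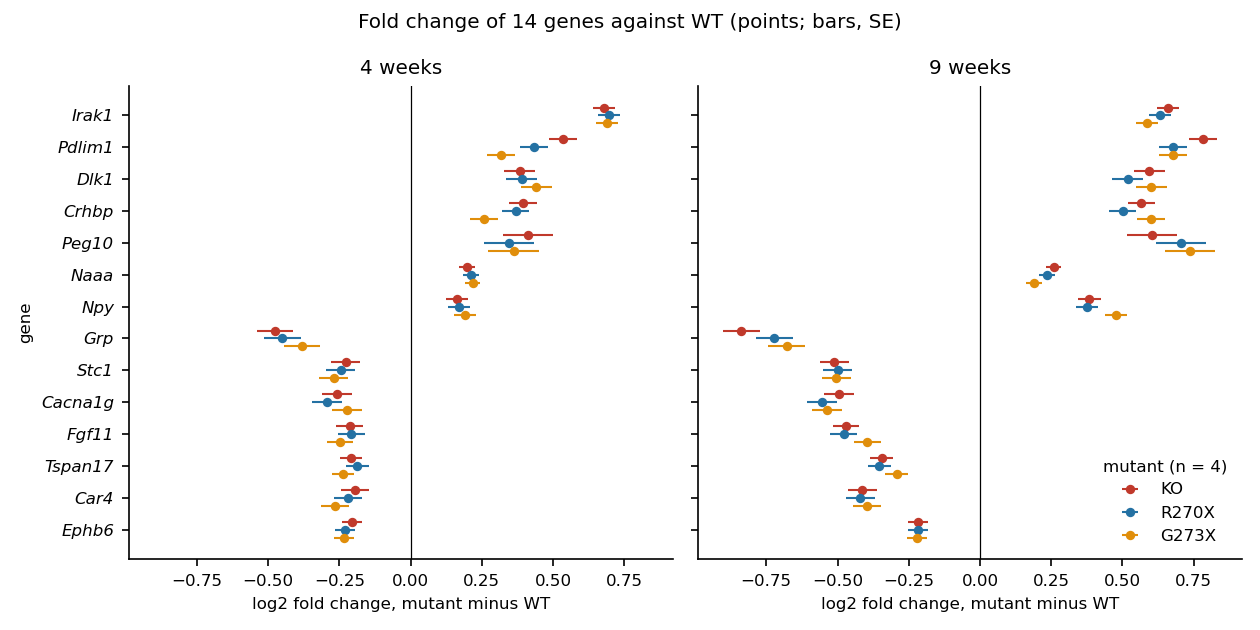
Log2 fold change against WT (points, with the standard error as bars, n = 4 per group) of 14 genes at 4 weeks (left) and 9 weeks (right) in KO, R270X and G273X. Irak1 lay between 0.59 and 0.70 in all 6 comparisons, while Grp lay at −0.38 to −0.48 at 4 weeks and at −0.68 to −0.84 at 9 weeks.

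At 9 weeks the KO animals differed from WT in the same direction in these genes. Pdlim1 rose by 0.78 ± 0.05, a 1.72-fold change, Irak1 by 0.66 ± 0.04, Dlk1 by 0.59 ± 0.05, Crhbp by 0.57 ± 0.05 and Peg10 by 0.60 ± 0.09. The homeodomain gene Pbx3 rose by 0.65 ± 0.08, Arhgap10, a regulator of Rho GTPases, by 0.62 ± 0.09, and Efna5, an axon guidance ligand, by 0.53 ± 0.09. Grp fell by 0.84 ± 0.06, to 0.559 of the WT level, and Akr1c18, a steroid-metabolising enzyme, fell by 0.72 ± 0.10. Cacna1g fell by 0.49 ± 0.05, Stc1 by 0.51 ± 0.05, the transcription factor gene Npas1 by 0.43 ± 0.04, and Doc2a, a calcium sensor of transmitter release, by 0.48 ± 0.08. In limma Irak1 had adjusted p = 9.0e-12, Pdlim1 3.3e-11, Grp 2.5e-09 and Akr1c18 3.0e-05.

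The R270X and G273X animals at 9 weeks had values near these. Pdlim1 rose by 0.68 ± 0.05 in both genotypes, Irak1 by 0.63 ± 0.04 in R270X and 0.59 ± 0.04 in G273X, and Peg10 by 0.71 ± 0.09 and 0.74 ± 0.09. Grp fell by 0.72 ± 0.06 in R270X and by 0.68 ± 0.06 in G273X. Akr1c18 fell by 0.61 ± 0.10 and 0.63 ± 0.10, Cacna1g by 0.55 ± 0.05 and 0.54 ± 0.05, and Stc1 by 0.50 ± 0.05 in both. The kinase gene Sgk1, which glucocorticoids induce, rose by 0.50 ± 0.09 in R270X and by 0.46 ± 0.09 in KO. In G273X it was 0.15 above WT, which did not pass, and the difference of G273X from KO did not pass either (−0.31 ± 0.09, limma adjusted p = 1). Ifitm3, an interferon-induced membrane protein, rose by 0.63 ± 0.17 in G273X, while its values of 0.27 in KO and 0.32 in R270X did not pass. Its SD was 0.60 among the G273X arrays and 0.37 among the WT arrays. The SE takes the spread over all 32 arrays, so it understates the spread of these groups. The growth factor gene Bdnf did not pass in any genotype at either age, with values from −0.09 in R270X to 0.02 in G273X, both at 9 weeks.

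Inhibitory neuron markers moved in both directions at 9 weeks. In all 3 mutants Pvalb (0.29 ± 0.05 in KO), Npy (0.38 ± 0.04) and Sst (0.12 ± 0.03) rose, and Gad2 (−0.26 ± 0.03), Reln (−0.17 ± 0.04), Calb2 (−0.24 ± 0.06), Nos1 (−0.26 ± 0.04) and Htr3a (−0.26 ± 0.06) fell. Of the 23 markers 3 rose and 7 fell in KO, 3 rose and 8 fell in R270X, and 3 rose and 5 fell in G273X. The counts adjusted over the list alone were 5 higher and 10 lower, 3 and 9, and 4 and 9. The medians were −0.04, −0.09 and −0.07, with camera adjusted p = 0.024, 0.024 and 0.11, and adjusted p = 0.348, 0.308 and 0.706 with an estimated correlation. Fry's test for change in either direction gave adjusted p = 9.8e-25, 4.8e-23 and 8.0e-25 for these inhibitory markers. Fry does not set a list against the other genes, of which many changed too: 780, 976 and 757 of all 13393 passed in limma. Its values therefore do not set these markers apart from other genes.

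Some markers of oligodendrocyte precursors were lower at 9 weeks. Of 14, 3 fell in KO (Sox10, Gpr17 and Vcan), 3 in R270X (Gpr17, C1ql1 and Ptprz1) and 4 in G273X (Gpr17, Vcan, C1ql1 and Neu4), and none rose. Gpr17, a receptor of maturing precursors, fell by 0.30 ± 0.08, 0.26 ± 0.08 and 0.41 ± 0.08. Ptprz1 lies in the stretch of chromosome 6 described further on, where only R270X arrays were low. Of the 14, 4, 5 and 7 fell adjusted over the list alone. Camera gave adjusted p = 0.00011, 0.0021 and 4.6e-05, which became adjusted p = 0.264, 0.308 and 0.166 with an estimated correlation. Of 24 cholesterol synthesis genes Tm7sf2, Dhcr7 and Fads2 fell in each mutant (in KO by 0.19 ± 0.05, 0.14 ± 0.04 and 0.15 ± 0.03), and adjusted over the list alone 8, 3 and 3 fell. Camera placed the list lower (adjusted p = 5.1e-06, 0.024 and 0.0078), with adjusted p = 0.348, 0.646 and 0.706 with an estimated correlation.

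Glutamate receptor and synaptic vesicle genes that passed at 9 weeks were lower. In KO 2 of 36 glutamate receptor and scaffold genes fell, the receptor subunit Grin2d by 0.32 ± 0.05 and the scaffold Homer3 by 0.34 ± 0.05. In R270X 5 fell and in G273X 3, with none higher, and adjusted over the list alone the numbers of lower genes were 2, 7 and 6, with 1 higher in R270X. Of 34 synaptic vesicle genes 3, 4 and 3 fell, among them Doc2a and Rph3a (−0.22 ± 0.03, −0.25 ± 0.03 and −0.28 ± 0.03), and adjusted over the list alone 4 fell in each mutant and 4 rose in KO. Of 46 potassium channel genes 5 rose and 4 fell in KO, 5 rose and 5 fell in R270X, and 4 rose and 4 fell in G273X. The voltage-gated channel gene Kcnh1 rose by 0.16 ± 0.03 in KO, and Kcnip2, a channel partner, fell by 0.26 ± 0.04. Channel genes that rose numbered 9, 5 and 7 adjusted over the list alone, and those that fell 7, 9 and 6. Of 41 extracellular matrix genes, Hapln1 and Ncan, proteins of perineuronal nets, fell in all 3 mutants (Hapln1 by 0.31 ± 0.06, 0.27 ± 0.06 and 0.37 ± 0.06). In that list 4 fell in KO, 3 rose and 2 fell in R270X, and 5 fell in G273X, against 1 higher and 5 lower, 4 and 4, and 0 and 5 adjusted over the list alone.

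Of the 48 reported MeCP2-responsive genes, 12 rose and 4 fell in KO at 9 weeks, 11 rose and 5 fell in R270X, and 9 rose and 5 fell in G273X. The guidance receptor Robo2 (0.20 ± 0.03, 0.20 ± 0.03 and 0.17 ± 0.03) and the adhesion molecule Sdk1 (0.33 ± 0.05, 0.26 ± 0.05 and 0.26 ± 0.05) rose, and the serotonin receptor Htr1a (−0.33 ± 0.07, −0.36 ± 0.07 and −0.33 ± 0.07) fell. Adjusted over the list alone, 16, 14 and 14 rose and 9, 6 and 7 fell, and fry gave movement upwards with adjusted p = 7.7e-05, 0.0016 and 0.00074. Fry does not set a list against the other genes, and camera with an estimated correlation did not call this list. In the simulated data fry called 2 of 27 lists in KO against WT at each age, where camera called 0. Of 32 genes flanking Mecp2, Irak1 rose and L1cam, a cell adhesion molecule, fell in all 3 mutants (L1cam by 0.15 ± 0.03, 0.12 ± 0.03 and 0.13 ± 0.03). In that list 2 rose and 1 fell in KO, 2 rose and 2 fell in R270X, and 1 rose and 2 fell in G273X. Adjusted over the list alone these were 3 and 2, 2 and 2, and 1 and 3.

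In limma 780 genes passed in KO at 9 weeks (512 higher, 268 lower), 976 in R270X (512 higher, 464 lower) and 757 in G273X (415 higher, 342 lower). Each of these genes had the same sign in both runs, again a weak check for genes called on the mean over both runs. Of the called genes, 9, 8 and 9 changed by more than 1.5-fold. Quantile normalization gave splits of 377 higher and 421 lower in KO, 436 and 663 in R270X, and 353 and 599 in G273X. Without 2 arrays that stood apart, a choice made after the data were seen, they were 284 and 265, 250 and 420, and 230 and 342, so higher genes no longer prevailed in R270X and G273X. Without WT replicate 2 alone they were 269 and 251, 226 and 397, and 194 and 306, and without WT replicate 1 alone 813 and 245, 790 and 424, and 641 and 294. Without WT replicate 4 they were 352 and 236, 327 and 391, and 266 and 272. The R270X split was 271 and 286 without R270X replicate 1, and 313 and 358 without R270X replicate 2. The KO count was 475 without KO replicate 2 and 490 without KO replicate 4. The R270X count was 623 without WT replicate 2, 557 without R270X replicate 1 and 613 without R270X replicate 3. The G273X count was 500 without WT replicate 2, 438 without G273X replicate 2 and 486 without G273X replicate 4. Without a run term the 3 counts were 360, 388 and 283, and with only the arrays compared 64, 150 and 78. Within the first run alone they were 43, 33 and 25, and within the second run 75, 86 and 53.

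The mutants were next compared with each other, which asks whether a truncated protein left expression different from its absence. At 4 weeks no gene passed in limma between R270X and KO (1096 had an unadjusted p under 0.05) or between G273X and R270X (1101). Plekha5, a pleckstrin homology domain gene, fell by 0.23 ± 0.03 and Zfp804a, a zinc finger gene, fell by 0.23 ± 0.04 in G273X against KO (adjusted p = 0.0048 and 0.036). At 9 weeks Plekha5 was the only gene that passed between G273X and KO, at −0.24 ± 0.03 (adjusted p = 0.0022), and it fell by 0.19 ± 0.03 in G273X against R270X (adjusted p = 0.023). Plekha5 was 0.25 ± 0.03 above WT in KO and 0.20 ± 0.03 in R270X at 9 weeks, while its value in G273X was 0.01. The G273X and KO count at 4 weeks was 1 without KO replicate 1, 2, 3 or 4 or G273X replicate 3, 0 without G273X replicate 2 or 4, and 140 without G273X replicate 1, and 670 with array weights. Of arrays outside the comparison, leaving out WT replicate 2 at 9 weeks gave 427 and WT replicate 1 at 4 weeks 4. The count was 1 without R270X replicate 2 or 3 at 4 weeks, or R270X replicate 2 or 4, KO replicate 1, WT replicate 1 or any G273X replicate at 9 weeks. It was 0 without a run term, 0 within the first run and 1094 within the second. The G273X and R270X count at 4 weeks was 2 without KO replicate 2 at 9 weeks, and 1 without G273X replicate 1 or 2, R270X replicate 1 or WT replicate 1 or 2 at 9 weeks. Array weights gave 7 for this comparison, and it was 2 within the first run and 4 without R270X replicates 3 and 4 together, a choice made after the data were seen. The R270X and KO count at 4 weeks was 501 with array weights, 137 with only the arrays compared, and 4 within the first run and without those 2 arrays. It was 1 without R270X replicate 4 alone, and the G273X and KO count at 9 weeks was 2 without G273X replicate 4. The latter was 0 without a run term and within each run alone.

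At 9 weeks R270X differed from KO in 5 genes, all lower in R270X and all neighbours on chromosome 6. Cadps2, a factor of dense-core vesicle release, was at −0.81 ± 0.11 (limma adjusted p = 2.8e-04). Ptprz1, a receptor phosphatase of glia, was at −0.76 ± 0.11 (3.8e-04), Aass, an enzyme of lysine breakdown, at −0.72 ± 0.11 (0.0033), the secreted protein gene Fam3c at −0.71 ± 0.09 (9.4e-05), and Ndufa5, a subunit of respiratory complex I, at −0.56 ± 0.06 (2.6e-05). The same 5 genes were the ones that rose in G273X against R270X at 9 weeks, by 0.86 ± 0.11, 0.78 ± 0.11, 0.69 ± 0.11, 0.68 ± 0.09 and 0.53 ± 0.06. Iqub, the remaining tested gene of the stretch in the GRCm38.p6 annotation, was at −0.41 ± 0.14 in R270X against KO and did not pass. The nearest 5 tested genes on each side lay between −0.22 and 0.07. The mean of the 6 genes, relative to WT of the run, was −0.59 ± 0.09 (SD, n = 4) in R270X at 9 weeks. At 4 weeks it was −0.62 and −0.59 in R270X replicates 1 and 2, of the first run, and −0.05 and 0.00 in replicates 3 and 4, of the second. The G273X and R270X count of 6 was 10 without R270X replicate 4, and it was 3 within the first run alone.

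**Figure D2:**
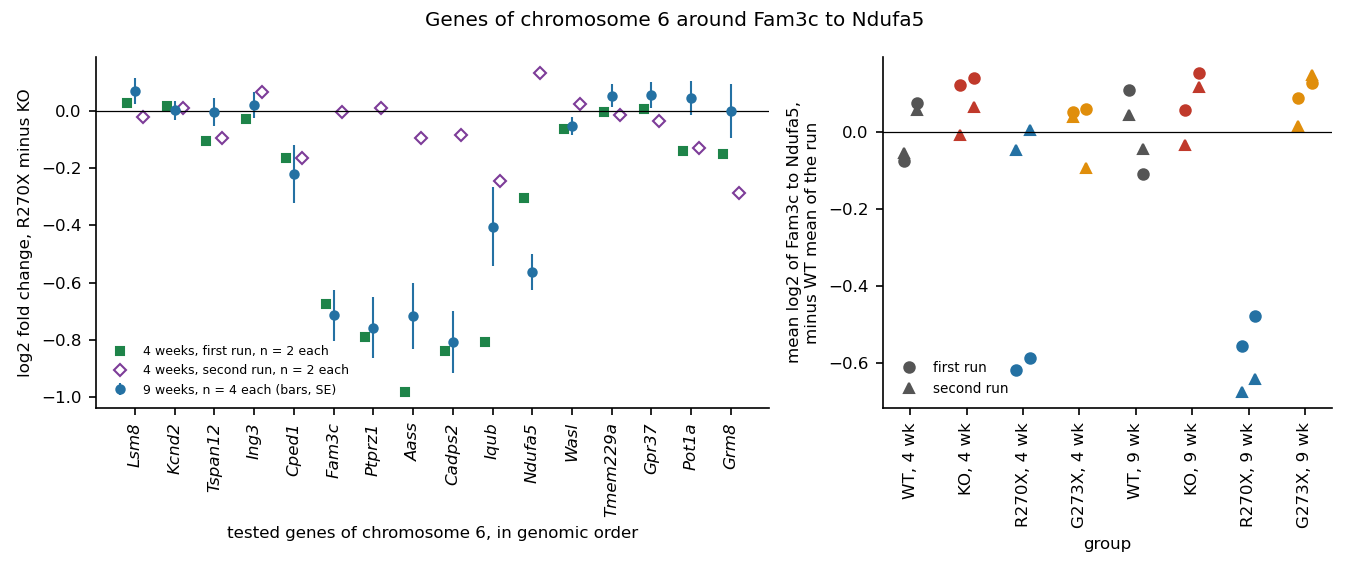
Left, log2 fold change of R270X against KO for 16 tested genes of chromosome 6 in genomic order (circles, 9 weeks with the standard error, n = 4 each; squares and diamonds, each run at 4 weeks, n = 2 each). Right, mean log2 of the 6 genes Fam3c to Ndufa5 relative to WT of the run for every array, where 6 of the 8 R270X arrays lie at −0.48 or lower.

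Gene lists also differed between mutants at 9 weeks. Of 22 myelin genes the median in G273X against R270X was −0.16, with Tspan2 at −0.28 and Mobp at −0.23, and none passed among all genes. Of the 22, 15 were lower adjusted over the list alone, and the list differed in camera with adjusted p = 6.5e-36 and adjusted p = 0.0054 with an estimated correlation. Against WT, the myelin list had 1 member higher in R270X (Mobp, 0.17 ± 0.05) and 3 lower in G273X (Mog, −0.26 ± 0.06, Myrf and Tspan2), or 3 higher and 5 lower adjusted over the list alone. Of 15 thalamus and habenula markers the median in R270X against KO was −0.15, and 5 were lower adjusted over the list alone (camera adjusted p = 9.7e-09, adjusted p = 0.0147 with an estimated correlation). These markers belong to a region beside the hippocampus. Against WT 4 of them rose and 1 fell in KO at 9 weeks, among them Rora at 0.41 ± 0.06, while 2 rose and 1 fell in R270X and in G273X. The counts adjusted over the list alone were 5 and 1 in KO, 3 and 4 in R270X, and 3 and 2 in G273X. A further list, 32 neuropeptides and trophic factors, was higher in G273X against R270X (median 0.03, camera adjusted p = 7.4e-06, adjusted p = 0.0054 with an estimated correlation), with the growth factor subunit Inhba at 0.31 ± 0.06 and Nptx2 at 0.23 ± 0.05, and 2 members passed adjusted over the list alone. These 3 list differences were the only ones of the 120 called by camera over all comparisons that held with an estimated correlation.

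A score built from the 100 genes most raised and the 100 most lowered in KO at the other age measured how far each array lay from WT towards KO. At 4 weeks the mean score was 0.301 ± 0.0322 (SD, n = 4) in KO, 0.232 ± 0.0366 in R270X and 0.222 ± 0.0568 in G273X, with WT at 0 ± 0.0572. At 9 weeks it was 0.420 ± 0.0541, 0.403 ± 0.0260 and 0.372 ± 0.0227, with WT at 0 ± 0.0480. Each mutant differed from WT at both ages in a two-sided exact permutation test, with p = 0.0286, the smallest that 70 splits allow, and the Benjamini-Hochberg value was 0.0286. That test does not keep the runs apart. Exchanging arrays only within runs, a choice made after the data were seen, allows 36 splits and no p below 0.0556, which each mutant reached against WT. R270X lay below KO at 4 weeks by −0.0689 (exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.171 over 6 pairs), with −0.0650 and −0.0728 in the 2 runs. No pair of mutants passed after adjustment. The other differences at 4 weeks were −0.0787 for G273X against KO (−0.0606 and −0.0967 in the 2 runs) and −0.00979 for G273X against R270X (0.00433 and −0.0239). At 4 weeks every R270X and every G273X array lay below both KO arrays of its run, and the exact permutation within runs gave both differences from KO p = 0.0556 (0.167 adjusted over 6 pairs). At 9 weeks G273X against KO was −0.0480 (−0.0621 and −0.0340), G273X against R270X −0.0309 (−0.0446 and −0.0172) and R270X against KO −0.0171 (−0.0174 and −0.0168). The adjusted p of G273X against WT at 4 weeks was 0.0571 without WT replicate 4.

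**Figure D3:**
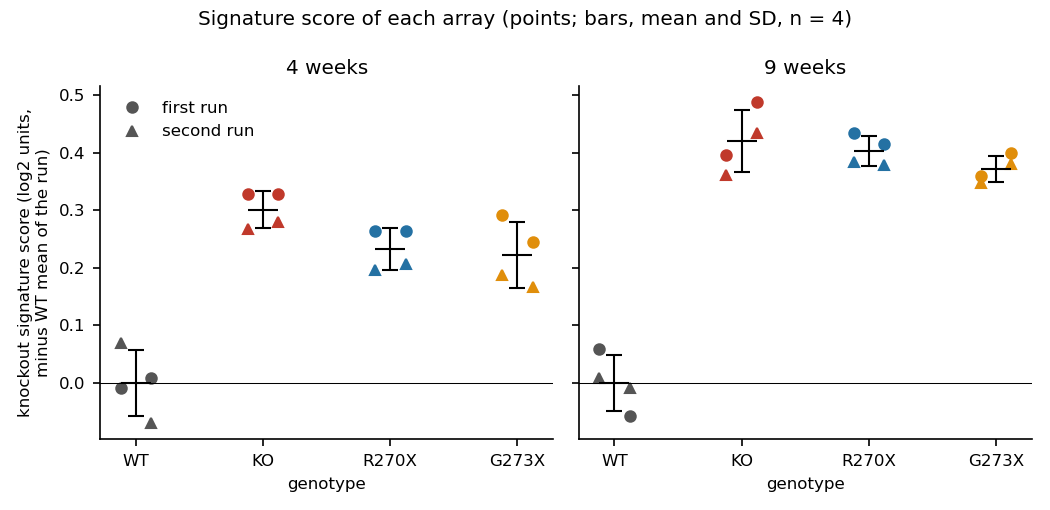
Knockout signature score of every array (points) with the group mean and SD (n = 4), relative to WT of the run. All mutant arrays lie above all WT arrays of their age.

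The 3 comparisons of an age share the WT arrays, which alone makes their gene lists overlap. At 4 weeks 9 genes were higher in all 3 mutants and 9 lower, of 137 genes that passed in any. The 9 lower genes were Ephb6, Fgf11, Gabra3, Grp, Reln, Rph3a, Rpp25, Stc1 and Tspan17. At 9 weeks 259 genes were higher and 165 lower in all 3, of 1366 in any. KO and R270X shared 330 higher and 210 lower genes at 9 weeks. Independent lists would share 19.6 and 9.28, and lists of the same sizes from simulated data with shared WT arrays and no effect shared 112 and 66.0 on average. The simulated genes were independent and the simulated arrays equally noisy, while WT replicate 2 at 9 weeks stood apart. All simulated values given here may therefore lie below what shared WT arrays alone produce in the real data. No gene was called in opposite directions in any pair. Across all genes, which are not independent replicates, the fold changes of KO and R270X at 9 weeks correlated with r = 0.867, those of KO and G273X with 0.855, and those of R270X and G273X with 0.874. Simulated data with shared WT arrays and no effect gave 0.502, and with the WT arrays split between both sides the values were 0.319, 0.291 and 0.334. At 4 weeks r was 0.524, 0.246 and 0.548, and with split WT arrays it was 0.00122, −0.148 and −0.00745. The covariances were 0.00292, 0.00150 and 0.00262 at 4 weeks and 0.00878, 0.00830 and 0.00904 at 9 weeks, against 0.00185 in the simulation, so that of KO and G273X at 4 weeks lay below it.

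The ages were compared within each genotype to ask whether differences grew with time. The ages come from different runs and look normalized separately. An additive difference between runs cancels in a difference from WT, but a difference of scale does not. The sizes of change at the 2 ages therefore cannot be told apart from run or processing. The 104, 70 and 26 genes that passed at 4 weeks in KO, R270X and G273X all had the same sign at 9 weeks. Of them 92, 53 and 21 passed there too, where lists of independent genes would share 3.59, 2.58 and 0.735. The 100 genes most raised and the 100 most lowered in 1 run at 9 weeks were followed in the other run, so that the choice of genes did not enlarge the 9-week change. Their 4-week change was 0.631 and 0.599 of it in KO, 0.363 and 0.530 in R270X, and 0.285 and 0.483 in G273X. Genes picked in the same way at 4 weeks had 9-week changes of 1.84 and 1.28 times their held-out 4-week change in KO, and 1.79 and 0.991 times in R270X. In G273X the ratio was 1.91 for the pick in the first run, and the pick in the second run did not hold, at −0.0124 in the other run and −0.0769 at 9 weeks. Across all genes, which are not independent, r between ages was 0.650, 0.301 and 0.0204. In the test of the change itself, limma called no gene in KO (547 with unadjusted p under 0.05) or R270X (1491) and 11 in G273X. In G273X the log2 fold change from WT moved up by 0.36 ± 0.07 for Pdlim1 (0.32 at 4 and 0.68 at 9 weeks), by 0.34 ± 0.07 for Crhbp (0.26 and 0.60) and by 0.37 ± 0.06 for the adhesion molecule Cntn4 (0.00 and 0.37). For Cdh12, another adhesion molecule, it moved by 0.48 ± 0.10 and changed sign, from −0.14 to 0.34. It moved down by −0.36 ± 0.07 for Cybrd1, an iron reductase (−0.02 and −0.38), and by −0.26 ± 0.04 for Xkr4 (−0.01 and −0.27), so these differences also became larger in size. The adjusted p of the 11 genes lay between 0.023 and 0.049. Without G273X replicates 1, 2, 3 and 4 at 4 weeks the count of 11 became 49, 0, 0 and 1, and without WT replicates 1, 2, 3 and 4 at 4 weeks it became 73, 0, 0 and 6. Without WT replicates 1, 2, 3 and 4 at 9 weeks it was 5, 0, 22 and 2, and without G273X replicates 1, 2, 3 and 4 at 9 weeks 0, 0, 6 and 0. Within each run alone it was 0. Of arrays outside the comparison, it was 3 without KO replicate 1, 2 or 4 or R270X replicate 1, 3 or 4 at 4 weeks, or KO replicate 4 or R270X replicate 2 or 4 at 9 weeks, and 4 without R270X replicate 1 at 9 weeks. The KO count was 1 without WT replicate 2 at 4 weeks. The R270X count was 19 without that array, 2 and 1 without R270X replicates 1 and 2 at 4 weeks, 3 without WT replicate 2 at 9 weeks and 1 without R270X replicate 3 at 9 weeks, and 2 without KO replicate 3 at 4 weeks or KO replicate 2 at 9 weeks.

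Gene length was examined because MeCP2 loss has been tied to higher expression of long genes. At 9 weeks the genes that rose in KO had a median length of 104 kb and those that fell 16 kb, against 24.3 kb for all genes with a length. The medians were 82.4 and 17.3 kb in R270X, and 91.3 and 18.3 kb in G273X. Of 483 genes longer than 300 kb, 94 rose and 7 fell in KO, and of 3215 genes shorter than 10 kb, 35 rose and 88 fell. Spearman's rho between length and fold change, across genes that are not independent, was 0.295 in KO (0.292 and 0.173 in the 2 runs), 0.276 in R270X (0.280 and 0.160) and 0.25 in G273X (0.234 and 0.181). At 4 weeks it was 0.215 in KO (0.20 and 0.164), −0.0105 in R270X (0.0800 and −0.0881) and −0.0797 in G273X (0.119 and −0.167), so in R270X and G273X it changed sign between runs. Without 2 arrays that stood apart, a choice made after the data were seen, rho at 9 weeks was 0.197, 0.188 and 0.153, and in G273X at 4 weeks 0.0242.

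**Figure D4:**
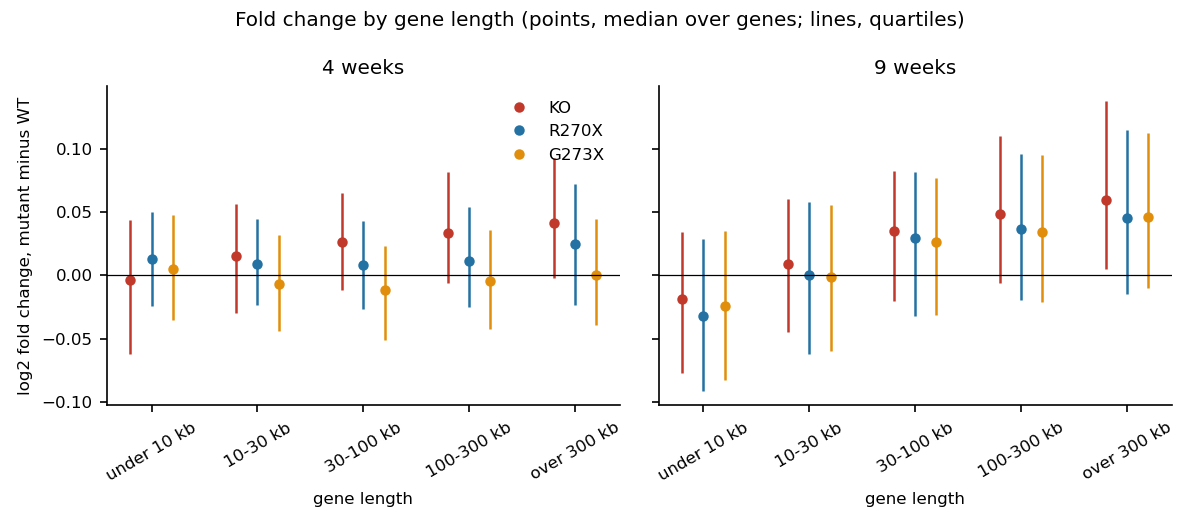
Median log2 fold change against WT (points, with quartiles as bars) of genes in bins of annotated length, for each mutant and age. In KO at 9 weeks the median was −0.02 for genes shorter than 10 kb and 0.06 for genes longer than 300 kb.

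Last, WT animals of 9 weeks were compared with WT animals of 4 weeks. All arrays of 1 age come from other runs than those of the other age, and the ages look normalized separately, so age cannot be told apart from run or processing in any value of this comparison, the myelin genes included. The median over all genes was −0.16 in the deposited values, 0.01 after quantile normalization and 0.07 after median centring, so values are read relative to that shift. Of the 27 lists, myelin genes had the lowest median. Of 22, 21 fell and 1 rose, with a median of −1.005 (camera adjusted p = 3.2e-18, adjusted p = 0.064 with an estimated correlation). Ugt8a, which makes the main myelin lipids, fell by 1.72 ± 0.11, and Enpp6, a marker of newly formed oligodendrocytes, fell by 1.41 ± 0.13. The myelin genes Opalin, Fa2h and Mog had values of −1.34 ± 0.13, −1.2 ± 0.11 and −1.17 ± 0.08. Of 14 oligodendrocyte precursor markers 12 fell (median −0.41, camera adjusted p = 5.5e-06, adjusted p = 0.064 with an estimated correlation), and of 24 cholesterol synthesis genes 21 fell (median −0.43, camera adjusted p = 3.1e-07, adjusted p = 0.393 with an estimated correlation). Adjusted over each list alone, 21, 13 and 21 fell. The small noncoding RNAs Snora3 (0.63 ± 0.16), Rmrp (0.60 ± 0.10) and Snora7a (0.51 ± 0.13) rose. In limma 6827 genes passed, 309 higher and 6518 lower. Quantile normalization gave 1802 higher and 1530 lower, and median centring 3432 higher and 847 lower, with 1835 and 1209 of the genes shared with the deposited scale.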

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

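The divisions of the arrays, save for those within runs and for conditions added to their reading, the test of larger changes at 9 weeks and the tests of gene length were planned before their results were seen, and all tests of the chromosome 6 stretch and those of spread and of single arrays at 9 weeks were chosen after the result was seen. The screen for far arrays covered 176 groups of 4 arrays, over the score, 10 marker lists and 11 genes. It found 9 arrays whose gap to the nearest other array, as a share of the range of their group, passed a limit that chance passes in about 5% of groups. Aass was far from the rest in G273X replicate 3 at 4 weeks, with a gap of 0.873 of the range, and in KO replicate 4 at 9 weeks, with 0.865. Cadps2 was far in KO replicate 1 at 9 weeks, with 0.847. Pdlim1 was far in KO replicate 2 at 9 weeks, with 0.902, and Stc1 in WT replicate 4 at 4 weeks, with 0.916. The mean of microglia markers was far in G273X replicate 2 at 9 weeks, with 0.885, and that of oligodendrocyte precursor markers in WT replicate 2 at 4 weeks, with 0.931. The mean of striatum and neocortex markers was far in G273X replicate 3 at 9 weeks, with 0.865, and in R270X replicate 3 at 4 weeks, with 0.918.

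The difference from WT changed between 4 and 9 weeks in 11 genes of G273X by the test of the change itself. The change was 0.48 for Cdh12, 0.388 for Cntn3, 0.373 for Cntn4, 0.361 for Pdlim1, 0.344 for Crhbp, 0.332 for Aff2, 0.284 for Npy and 0.212 for Atrnl1. It was −0.257 for Xkr4, −0.284 for Apcdd1 and −0.362 for Cybrd1.

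Other divisions of the same 8 arrays into 4 and 4 were fitted for each comparison, 35 in all with the real one. These also move arrays between runs, and the 18 that keep 2 arrays of each run on each side allow no share below 0.0556, so within runs the divisions are too few to exclude chance in any comparison. The other divisions of the 35 are uneven over runs, which differ in expression, and no adjustment was made over comparisons. A real division that alone gave its count among all 35 therefore leads the others but does not exclude chance. This was so for R270X against WT at 4 weeks (1 of 35 divisions, 70 genes, highest other 1). The same held at 9 weeks for R270X against WT (976, highest other 8), G273X against WT (757, highest other 7), R270X against KO (5, highest other 0) and G273X against R270X (6, highest other 0), and for age in WT (6827, highest other 1521), where age cannot be told apart from run. The real division was also alone at 4 weeks for KO against WT (104, highest other 73), G273X against WT (26, highest other 22) and G273X against KO (2, highest other 0), but with 1 array left out these counts fell as low as 37, 14 and 0, so the lead over other divisions leaves their size open. Other animals gave many of the same genes: 92 of the 104 of KO, 53 of the 70 of R270X and 21 of the 26 of G273X were called again with the same sign at 9 weeks. Lists of independent genes would share 3.59, 2.58 and 0.735. Genes are not independent and both ages use the same estimate of spread per gene, so these values do not measure chance. Between G273X and KO, Plekha5, 1 of the 2 genes, was called again too, and was the only gene at 9 weeks. Chance cannot be excluded by the divisions for the count of KO against WT at 9 weeks, where 2 of 35 gave as many as the real 780. The other, with 1265 genes, set WT replicates 2 and 4 with KO replicates 1 and 3 against the rest and holds both runs equally, so it shows a structure of the arrays beside genotype. The same 92 genes go with a KO difference at 9 weeks but do not measure chance, and they leave the size of the count open. Of the 780, 747 had the same sign at 4 weeks. The score from genes picked at 4 weeks put the lowest KO array of 9 weeks at 0.362 and the highest WT array at 0.0582. The divisions do not exclude chance for a count of 1 in G273X against KO at 9 weeks (2 of 35, highest other 1), though the repeated call of Plekha5 in other animals argues against it for that gene. Chance cannot be excluded for the change of G273X between ages (11 genes, 6 of 100 divisions drawn, highest other 459). A real count of 0 is reached by every division, so the divisions decide nothing, a reading added after the values were seen, for R270X against KO (35 of 35, 0 genes, highest other 0) and G273X against R270X at 4 weeks (35 of 35, 0 genes, highest other 1). The same holds for the changes between ages in KO (100 of 100, 0 genes, highest other 2138) and R270X (100 of 100, 0 genes, highest other 19).

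A stretch of 6 neighbouring genes of chromosome 6, Fam3c to Ndufa5, was lower in 6 of 8 R270X arrays. Exchanged labels are argued against, since 0 of the 12 arrays of other groups at 4 weeks was low by 0.3 or more, and so is a difference between runs, since the deposited values of these 12 arrays were −0.0151 ± 0.0405 (SE) in the first run against the second, where R270X arrays were at −0.66. A change of the region itself in most R270X animals, such as a copy number change or the insertion site of the transgene, stays open as a hypothesis: of 4 other R270X animals, at 4 weeks, 2 were low, with genes inside at −0.98 to −0.31 against KO of their run and neighbours at −0.17 to 0.03. The 9-week values cannot test it, since they delimit the stretch, and a first bound on them, which Cped1 missed at −0.22 ± 0.10, was given up after the values were seen. For R270X replicates 3 and 4 at 4 weeks, at −0.049 against KO of their run, KO animals recorded as R270X cannot be told apart from R270X animals without the change, because both give this value, and their scores of 0.196 and 0.206, below 0.267 and 0.280 in KO of the run, are 2 arrays against 2, where KO arrays of 1 run at 9 weeks lay at 0.396 and 0.488.

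More genes were called at 9 than at 4 weeks in each mutant. The ages come from different runs and look normalized separately, so sizes of change at the 2 ages cannot be told apart from run or processing. A larger spread among arrays at 4 weeks was not seen, since the residual SD at 4 weeks was 0.931 of that at 9 weeks. The fit has 1 estimate of spread per gene for both ages. A larger spread at 4 weeks would have raised the standard error at both ages, so it could not have lowered the 4-week counts alone in this way. Spread at 9 weeks also enters the 4-week counts. Without WT replicate 2 at 9 weeks the KO count at 4 weeks was 222, against 104 with it. That shared estimate also takes no account of the larger residual SD at 9 weeks. A single array at 9 weeks is argued against, since the lowest 9-week count with 1 array left out was 438 and the highest such count at 4 weeks 222. Larger changes at 9 weeks stay open as a hypothesis: genes picked in 1 run at 9 weeks had 4-week changes of 0.285 to 0.631 of their held-out 9-week changes in all 6 picks, under the bound of 0.8 set beforehand. Genes picked in 1 run at 4 weeks had 9-week changes of 1.28 to 1.91 times their held-out 4-week changes except in 1 run of R270X, where the ratio was 0.991. That ratio met the bound of 1 set beforehand, but by less than the spread of the ratios, a condition added after the values were seen together with leaving out 1 run of G273X whose held-out change was below 0.

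Longer genes were higher in mutants at 9 weeks. Another division of the arrays stays open for KO: 1 of 35 divisions, the real one, gave a correlation as far from 0, but its 0.295 passed the highest other, 0.290, by less than the SD of 16 pairs of arrays of 1 group and run, 0.0678, a spread chosen after the values were seen. Array-to-array differences stay open, because the highest correlation with length in such a pair was 0.203, below the smallest mutant value of 0.25 by less than that SD. The main axis of variation between such arrays stays open as well, since with it taken out the correlations were 0.208 in KO, 0.183 in R270X and 0.153 in G273X, between the bounds set for either verdict. The design gives a biological explanation, the loss of MeCP2, which may act beside these and cannot be told apart from them here.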

How the results depend on the processing

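The arrays left out for standing apart, the R270X arrays left out for lacking the chromosome 6 difference, the arrays left out of groups outside a comparison and the permutation within runs were chosen after the data were seen, and the other settings before. Arrays give no depth, and genes near background were limited by the filter on mean signal. For the called genes named by the rule, 6557 values were obtained under the alternatives, over 152 genes and comparisons. Of these values 5728 passed, 829 had the same sign but did not pass and 0 had the opposite sign. The values within each run alone, 142 for each run, were of genes called with the same sign in both runs. Those values had no room to reverse, so they do not test direction. A further 4624 values had 1 array left out. All named genes were already called over all arrays, so the 0 is a weak check of direction. Values below are in the order KO, R270X and G273X at 4 weeks, then at 9 weeks, where 6 are given for mutants against WT. Total counts that are not given stayed within 1.5 times the main count, apart from those with 1 array left out, which are given as ranges. Except where a setting has fewer arrays or another number of genes tested, the cause was not tested.

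Without a run term the 6 counts were 28, 17, 6, 360, 388 and 283, against 104, 70, 26, 780, 976 and 757 in the fit with it. G273X against KO was 0 at both ages, and the change of G273X between ages 1. With only the first run they were 1, 4, 1, 43, 33 and 25, with 4 for R270X against KO, 0 for G273X against KO and 2 for G273X against R270X at 4 weeks, 0 for G273X against KO and 3 for G273X against R270X at 9 weeks, and 0 for the change of G273X. Length correlations were 0.080 in R270X and 0.119 in G273X at 4 weeks. With only the second run they were 5, 2, 51, 75, 86 and 53, with 1094 and 0 for G273X against KO at 4 and 9 weeks, and 4 and 0 for the changes of R270X and G273X. Length correlations were 0.164 in KO at 4 weeks, and 0.173, 0.160 and 0.181 at 9 weeks. With only the arrays compared they were 3, 5, 1, 64, 150 and 78, with 137 and 0 for R270X and G273X against KO at 4 weeks, 0 for G273X against KO at 9 weeks and 0 for the change of G273X. These settings have fewer arrays to estimate the spread, apart from the one without a run term.

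With the replicate number as a block in place of the run term, the counts were 76, 56, 27, 706, 880 and 673, with 7 for G273X against R270X at 9 weeks, and 2 and 7 for the changes of R270X and G273X between ages. Arrays with the same number correlated above 0.1 in 15 of 24 pairs at 4 weeks and 21 of 24 at 9 weeks, and in 6 and 8 of 24 with the run removed. With 2 arrays per group and run, removing the run makes their deviations mirror images, so each of these values is counted for 2 pairs. Whether the numbers pair the animals therefore cannot be told from these values.

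Without a filter the counts were 48 for KO and 43 for R270X at 4 weeks, 2 and 5 for R270X and G273X against KO at 4 weeks, 0 for the change of G273X and 11695 for age in WT, and the length correlations 0.261 for KO at 4 weeks and 0.286 for G273X at 9 weeks. With the 60th percentile they were 4 for G273X against KO and 1 for G273X against R270X at 4 weeks and 4205 for age in WT, with length correlations of 0.140 and 0.0351 in KO and R270X at 4 weeks and 0.198 in G273X at 9 weeks. Quantile normalization gave 125 for R270X and 51 for G273X at 4 weeks, 1 for G273X against KO at 4 weeks, 17 for the change of G273X, 3332 for age in WT and a length correlation of 0.0313 in R270X at 4 weeks. Its KO count of 127 at 4 weeks and counts of 798, 1099 and 952 at 9 weeks had other splits of higher and lower genes. Median centring gave 63, 47 and 17 at 4 weeks, 408 higher and 305 lower genes in R270X at 9 weeks, 0 for the change of G273X and 4279 for age in WT. The mean of probe sets gave 3 for the change of G273X. A trend with robust moderation gave 4 for G273X against KO and 1 for G273X against R270X at 4 weeks, and 17 for the change of G273X. Array weights gave 106 for R270X at 4 weeks, 501, 670 and 7 for R270X against KO, G273X against KO and G273X against R270X at 4 weeks, 10 for G273X against R270X at 9 weeks, and 13 and 2 for the changes of R270X and G273X.

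Without WT replicate 2 at 9 weeks and G273X replicate 4 at 4 weeks, which stood apart, the counts were 295 for KO and 113 for R270X at 4 weeks, 1 for G273X against KO at 4 weeks, and 1 for the changes of KO and of G273X. The splits of higher and lower genes at 9 weeks were 284 and 265 in KO, 250 and 420 in R270X, and 230 and 342 in G273X, against 512 and 268, 512 and 464, and 415 and 342. Length correlations were then 0.0242 in G273X at 4 weeks and 0.197, 0.188 and 0.153 at 9 weeks. Without R270X replicates 3 and 4 at 4 weeks, the counts were 15 for R270X against WT and 4 each for R270X against KO and G273X against R270X. The R270X score was then 0.264 above WT with an adjusted p of 0.0667, where 2 arrays against 4 cannot pass the threshold. With WT arrays split, the correlations between mutants were 0.00122, −0.148 and −0.00745 at 4 weeks and 0.319, 0.291 and 0.334 at 9 weeks, as the shared arrays no longer add to them. Over genes called in either mutant they were 0.943, 0.909 and 0.934 at 4 weeks, because such genes were chosen by their size.

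With each array left out in turn, including those of groups outside the comparison for all counts but that of age in WT, the counts against WT at 4 weeks ranged from 37 (without KO replicate 2) to 222 (without WT replicate 2 at 9 weeks) in KO, from 30 (without WT replicate 1) to 151 (without WT replicate 2) in R270X, and from 14 (without G273X replicate 4) to 42 (without WT replicate 2 at 9 weeks) in G273X. At 9 weeks they ranged from 475 (without KO replicate 2) to 1058 in KO, from 557 (without R270X replicate 1) to 1214 in R270X and from 438 (without G273X replicate 2) to 935 in G273X, each highest without WT replicate 1. R270X against KO ranged from 0 to 1 at 4 weeks and from 5 to 7 at 9 weeks. G273X against KO ranged from 0 to 427 (without WT replicate 2 at 9 weeks) at 4 weeks and from 1 to 2 at 9 weeks. G273X against R270X ranged from 0 to 2 (without KO replicate 2 at 9 weeks) at 4 weeks and from 5 to 10 (without R270X replicate 4) at 9 weeks. The changes between ages ranged from 0 to 1 in KO, from 0 to 19 (without WT replicate 2 at 4 weeks) in R270X and from 0 to 73 (without WT replicate 1 at 4 weeks) in G273X, and age in WT from 6290 to 7016. Only arrays of the compared groups were left out for the score. The score against WT ranged from 0.266 to 0.336, from 0.197 to 0.267 and from 0.188 to 0.257 at 4 weeks, and from 0.391 to 0.449, from 0.374 to 0.432 and from 0.343 to 0.401 at 9 weeks. R270X against KO ranged from −0.0801 to −0.0567 and from −0.0365 to 0.00552, G273X against KO from −0.102 to −0.0600 and from −0.0674 to −0.0254, and G273X against R270X from −0.0329 to 0.00892 and from −0.0400 to −0.0207. With permutation within runs, the scores of 0.301, 0.232, 0.222, 0.420, 0.403 and 0.372 above WT had p = 0.0556, the smallest that 36 splits allow, so this setting cannot pass the threshold. The 143 list results called by camera or fry were tested again with camera alone, so only the 120 calls of camera could be lost. Quantile normalization lost 20 and gained 3, and median centring lost 8 and gained 6. Of 116 results so tested, 7 were lost and 1 gained without a run term, and 2 were lost with the block. With an estimated correlation camera lost 117 of its 120 calls, a setting in which direction cannot turn. In the other settings 0 list results turned direction.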

Other observations

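All lists were fixed before the data were examined, and no test was added in this part. Some gene groups had few members past the threshold over all genes at 9 weeks. Of 28 immediate early genes 2 rose in KO (Fosl2, 0.21 ± 0.05, and Ptgs2, 0.32 ± 0.09), 0 in R270X and 3 in G273X (Fosl2, Ptgs2 and Nr4a2), with the same numbers adjusted over the list alone. Of 22 glucocorticoid-responsive genes 3 rose in KO and in R270X (Sgk1, the metallothionein Mt1 and Errfi1) and 1 in G273X (Errfi1, 0.25 ± 0.05), and 3, 4 and 1 adjusted over the list alone. The difference between G273X and the other mutants did not pass in Sgk1 and was not tested for the list counts. Of 13 interferon-stimulated genes 1 rose in KO (Ifit3, 0.34 ± 0.10), 0 in R270X and 3 in G273X (Ifitm3, Ddx58 and B2m), and 1, 2 and 4 adjusted over the list alone. Of 18 circadian genes Hlf rose in KO (0.17 ± 0.05) and R270X (0.18 ± 0.05), and adjusted over the list alone 10, 1 and 0 rose. Of 14 GABA receptor genes the metabotropic subunit Gabbr1 fell in each mutant (−0.09 ± 0.03 in KO), as did Gabra3 and Gabbr2 in R270X, and adjusted over the list alone 3, 4 and 3 fell while 0, 1 and 1 rose. Of 32 neuropeptides and trophic factors, Npy and Sst rose and Nptx1 and Scg2 fell in each mutant, in all 2 rose and 3 fell in KO and R270X and 3 rose and 2 fell in G273X. The counts adjusted over the list alone were 2 higher and 5 lower, 2 and 3, and 3 and 2.

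Among cell type lists at 9 weeks, the pyramidal cell genes Wfs1 (−0.30 ± 0.05 in KO) and Bok (−0.35 ± 0.05) fell in each mutant, and of 20 excitatory markers 2, 3 and 2 fell, or 4, 5 and 3 adjusted over the list alone. Of 20 astrocyte markers 1 rose in KO and R270X (F3) and 2 fell in G273X (Gja1 and S100b), or 1, 1 and 5 adjusted over the list alone with 1 more higher in G273X. Of 16 microglia markers only Trem2 and Fcrls fell, in R270X, and of 20 endothelial and mural markers only Pecam1 rose, in each mutant (0.20 ± 0.05 in KO). The same numbers held adjusted over each list alone. Of 14 striatum and neocortex markers 4 rose in KO, 3 rose and 1 fell in R270X, and 3 rose in G273X, among them Foxp1 (0.18 ± 0.03 in KO). The corresponding counts adjusted over the list alone were 6 and 1, 3 and 1, and 3 and 1. None of 18 choroid plexus markers passed at 9 weeks, with medians of 0.13, 0.11 and 0.16, and none of 40 ribosomal protein genes, by either adjustment. Of 55 oxidative phosphorylation genes 0, 1 and 1 passed, Ndufa5 of the chromosome 6 stretch lower in R270X and Cyc1 higher in G273X, of which the first passed adjusted over the list alone. Of 26 chaperones 0, 1 and 2 rose (Dnaja1, and Bag3 in G273X), and of 35 chromatin genes 1, 2 and 1 rose, among them Hdac9 (0.21 ± 0.03 in KO), with the same numbers adjusted over each list alone.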
